A study of Oryzias latipes with 6 samples.

How the data were processed

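RNA from the testes of medaka (Oryzias latipes) was sequenced in 6 libraries, 3 from wild-type fish and 3 from nphp4 mutant fish, and each library pooled the testes of 2 fish. Total RNA was isolated with TRIzol, per the labels' protocols. The deposited table holds 1 FPKM value (fragments scaled to gene length and library size) per gene and library, made by the authors, for 24365 genes with Ensembl medaka identifiers. Each gene also has the deposited gene length in bases, a quantity of another kind that the authors used as the divisor of the FPKM. Raw read counts were not used here. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without saying which step each tool did. No genome build, annotation release or strand setting is named in the labels, so coordinates are given as the deposited table gives them.

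The FPKM values keep the read counts behind them. Multiplied by the gene length, 100% of the values above 0 in every library were whole multiples of the value of 1 read, within 0.01 read. The whole reads recovered this way came to 16004325, 14691441 and 15516979 on genes in wild type 1, 2 and 3, and to 13871313, 13438879 and 16054354 in mutant 1, 2 and 3. The library totals inside the deposited FPKM values were 16639681, 15259087, 13693794, 14307139, 13670728 and 16355706 reads in the same order. Each of them equals the library's median-ratio size factor times 14894653, the geometric mean of the 6 read totals. The deposited FPKM values are therefore already scaled by median-ratio size factors, and scaling again by such factors changes nothing. No read fell on 2168 genes in any library.

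Gene symbols came from the deposited table. Of 8821 genes named there by an identifier alone, 682 received a symbol through their NCBI gene number in the RefSeq table of the assembly ASM223467v1, which left 16226 genes with a symbol. Of 3560 genes with such a number, 98.3% overlapped the RefSeq gene on the same chromosome. Protein names given for genes without a symbol are the best Swiss-Prot matches in the deposited table. The gene with the nephrocystin-4 match has no symbol in the table. It overlaps nphp4 of RefSeq and is called nphp4 here.

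The groups were compared with limma 3.58.1 in R 4.3.3, as a linear model of log2(FPKM + 1) with an intensity trend and robust empirical Bayes moderation, with no covariate. The test took 15203 genes with a mean of at least 1 FPKM in either group. Genes were called at a Benjamini-Hochberg adjusted p (false discovery rate, FDR) below 0.05. Log2 differences are on the log2(FPKM + 1) scale, mutant minus wild type, which understates the change of genes with low values. SE is the moderated standard error, and SD is the standard deviation over the 3 libraries of a group. This design was the one fixed before the data were examined for the case that a table gives normalized values. The count models fixed for raw counts were not fitted, and of the count methods only limma-voom was run, on the recovered reads. A group with no reads was given a floor of 3 reads over the whole group, and a ratio to 1 to 3 reads has a 95% binomial interval. Floors and intervals cover counting error only.

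26 gene lists were fixed before the data were examined. They covered cilia (nephronophthisis and transition zone, intraflagellar transport, motile axoneme), germ cells (spermiogenesis, meiotic prophase, spermatogonia), gonadal somatic cells (Sertoli, Leydig, ovary), signalling (hedgehog, Wnt, Hippo), cell junctions, cell cycle, apoptosis, DNA repair, macrophages and lymphocytes, interferon and complement, extracellular matrix, blood, endothelium and smooth muscle, other organs, oxidative phosphorylation, glycolysis, stress, and ribosomal proteins. Members were matched by symbol, with an a or b suffix allowed, and nphp4 was in no list. Through the entry rho (rhodopsin), this matching also placed the unrelated genes RHOA and RHOB in the list of other organs. Each list was tested with camera of limma at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. Chromosomes were compared with 2-sided Fisher's exact tests over the tested genes, adjusted over the chromosomes and the mitochondrial genome. The rule for named genes, also fixed before the data were examined, took nphp4, called genes with a symbol, a log2 difference of at least 1 and groups without overlap (at most 12 in each direction), the 4 members with the smallest p of each called list, called genes among the 50 most abundant, and called genes within 5 Mb of nphp4. Every other gene named was chosen after its values were seen.

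The tests were tried on simulated reads with the real means and library sizes for the comparison of mutant with wild type. The changed genes were drawn only from those above a minimum of mean reads, so their recovery does not speak for genes with few reads. Each simulated gene took the trend of spread at its mean level, and no library was made to stand apart. Recovery may therefore be higher than on the real data. On 14978 simulated genes, limma called 59 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, in the right direction. It also called 18 unchanged genes, which is 10.7% of its calls and above the nominal rate. Of the simulated lists, the one shifted 1.5-fold and 0 of 25 unshifted ones were called. Simulated genes varied independently, whereas the estimated correlation within the real list of ribosomal proteins was 0.78. The simulation therefore cannot show how often the list test makes false calls on the real data. The search for a breakpoint along a chromosome found a simulated block in 40 of 40 runs and a false one in 2 of 40. The test of neighbouring genes found simulated pairs in 20 of 20 runs and a false excess in 1 of 20.

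Alternatives fixed before the data were examined were scaling by library totals, no filter, a filter of at least 1 CPM (reads scaled to the library total) in at least 3 libraries, limma-voom, the replicate number as a block, leaving out each library in turn, a pseudocount of 0.1, an FDR of 0.01, a fold minimum, and the other list tests. Chosen after seeing the data were TMM scaling, library quality weights, an intestinal marker level as covariate, leaving out both libraries with intestinal transcripts, matching of lists also by Swiss-Prot name, lists of genes of 6 other tissues, and the share of genes at an unadjusted p below 0.05 on each chromosome. Breakpoints and neighbours were tested with 10000 permutations. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.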

Results

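Gene expression was measured by RNA sequencing in the testis of medaka, a small laboratory fish. 3 libraries came from wild-type fish and 3 from nphp4 mutant fish, each made from the pooled testes of 2 fish. Between 13438879 and 16054354 reads fell on genes in each library. The series design calls the mutant a knockout, and the labels used here do not describe the lesion. The comparison asks which transcripts of the testis differ between wild-type and mutant fish. nphp4 encodes nephrocystin-4, a protein of the transition zone at the base of cilia whose human gene is mutated in nephronophthisis.

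The transcript of nphp4 itself (ENSORLG00000023493, chromosome 7, 571495 to 671521, minus strand) was present in both groups. Its level was 17.6 ± 5.68 FPKM in wild type (SD, n = 3) and 8.26 ± 2.32 FPKM in the mutant (SD, n = 3). The wild-type libraries held 12.2 to 23.5 FPKM and the mutant libraries 6.84 to 10.9 FPKM, so every mutant library was below every wild-type library. The log2 difference was -0.99 (SE 0.27). For this gene, fixed in advance, the unadjusted p in limma was 0.00827. The adjusted p in limma was 0.436, so it did not pass the threshold over all genes. The 2-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. A gene on the opposite strand, ENSORLG00000026614, lies within nphp4, and counting by strand is not stated.

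9 genes differed between mutant and wild-type testis, 5 higher and 4 lower in the mutant. The lower genes included a pair of neighbours on chromosome 11 that match type-2 ice-structuring protein, a family with a C-type lectin fold. ENSORLG00000026380 (9656740 to 9657995) was at 115 ± 65.0 FPKM in wild type (SD, n = 3) and had no read in any mutant library, which makes it at least 973-fold lower (adjusted p = 0.00831, limma). ENSORLG00000022373 (9660229 to 9661222) was at 16.9 ± 7.31 FPKM in wild type and also had no mutant read, at least 119-fold lower (adjusted p = 0.0120, limma). Both lie within the span of CDCA7L on the same strand. A 5S ribosomal RNA gene (RF00001, ENSORLG00000029102, chromosome 3, 1685048 to 1685166) was at 58.8 ± 12.7 FPKM in wild type against no mutant read, at least 103-fold lower (adjusted p = 0.000126, limma). Reads of such copies can be assigned to one another, and the sum over all 62 annotated 5S genes was 2464 ± 856 FPKM in wild type and 1501 ± 445 FPKM in the mutant (SD, n = 3). ENSORLG00000023131 (chromosome 16, 29564348 to 29565052), a match to collagen XXVIII, held 177 reads in wild type and 2 in the mutant, a ratio of 86.1 (95% counting interval 23.5 to 716; adjusted p = 0.00186, limma).

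Of the genes that rose, 3 lay on chromosome 13. LSAMP, a cell adhesion protein of the limbic system (ENSORLG00000027838, 32928393 to 33022290), rose 6.12-fold, from 3.78 ± 1.35 to 23.2 ± 4.09 FPKM (SD, n = 3; log2 difference 2.36, SE 0.24, adjusted p = 0.0411, limma). si:ch211-132b12.2, which matches a GABA transporter (ENSORLG00000028327, 27909790 to 27923920), rose 45.2-fold, from 0.177 ± 0.165 to 7.98 ± 1.53 FPKM (adjusted p = 0.00831, limma). Beside it, ENSORLG00000029944 (28004795 to 28039412), a match to von Willebrand factor A domain-containing protein 5A, rose 9.06-fold to 5.64 ± 0.734 FPKM (adjusted p = 0.0133, limma). On chromosome 20, ENSORLG00000012644, a match to inositol monophosphatase 1, an enzyme that releases free inositol, rose 17.4-fold from 1.16 ± 0.141 to 20.1 ± 6.41 FPKM (adjusted p = 0.00831, limma). ENSORLG00000029947 on chromosome 19, a protein-coding gene without a match, rose 5.71-fold from 1.76 ± 0.711 to 10.1 ± 0.838 FPKM (adjusted p = 0.0433, limma). LSAMP, si:ch211-132b12.2 and ENSORLG00000029947 each overlap an unnamed gene on the other strand.

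In all 9 genes the groups did not overlap, which held for 2129 of the 15203 tested genes (14.0%) where chance gives 10%. 1084 genes had an unadjusted p below 0.05 in limma, 504 higher and 580 lower, where 5% of the tested genes is 760. Splits of the libraries that mix the genotypes gave 166 to 1362 such genes, so this count alone does not show an effect of genotype. No gene among the 50 most abundant was called. limma-voom on the recovered reads called 0 genes, with a smallest adjusted p of 0.151 and 1042 genes at an unadjusted p below 0.05. The count of calls was 4 without wild type 1, 18 without wild type 3, and 3, 2 and 2 without mutant 1, 2 and 3.

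**Figure D1:**
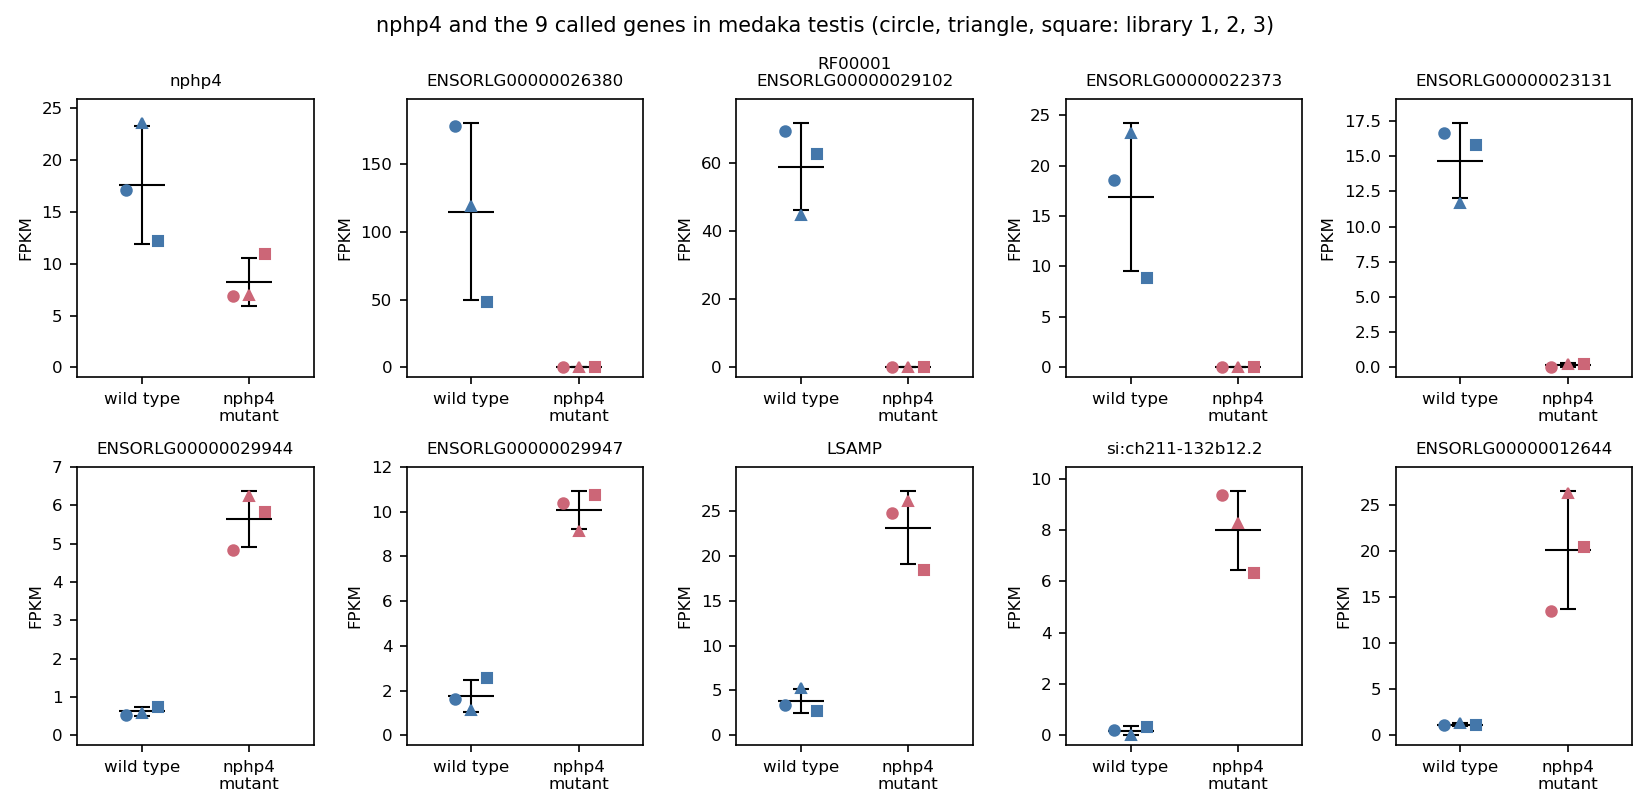
FPKM of nphp4 and of the 9 called genes in each library (points, 3 per group), with the group mean and SD (bars). The 4 genes that were lower in the mutant had 0 to 2 mutant reads in all, and in every panel the groups do not overlap.

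At a preset correlation, 7 of the 26 lists were called: nephronophthisis and transition zone, intraflagellar transport, meiotic prophase, cell cycle and DNA repair slightly higher in the mutant, and interferon and complement and ribosomal proteins lower. None of the 7 passed with an estimated correlation (adjusted p = 0.848 for each, camera of limma), nor did any list with fry (smallest adjusted p 0.875). No member of the 7 passed the threshold over all genes. Wild type 3 stood apart from the other 5 libraries in most of these lists. Its digestive gland genes were far above those of the rest, with trypsin (prss1) at 8632 FPKM against 156 to 1164, and elastase (CELA1) at 3667 FPKM against 39.9 to 584. The median correlation of its log2 values with the other libraries was 0.878, against 0.950 to 0.969 for the other 5. Mutant 3 was also far from the wild-type mean in some lists. In interferon and complement its mean log2 difference from the wild-type mean was -0.67, against 0.25 for wild type 3. In intraflagellar transport it was 0.38 for mutant 3 and -0.33 for wild type 3.

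The list of nephronophthisis and transition zone genes was higher by a mean log2 difference of 0.16, with 31 of 37 members positive (adjusted p = 0.0299, camera of limma; adjusted p = 0.848 with an estimated correlation). Its mean was 0.0160 without wild type 3 and 0.0639 without mutant 3 (adjusted p = 0.385), and without mutant 2 it stayed at 0.160 but was not called (adjusted p = 0.0807, camera of limma). bbs9, a part of the BBSome that carries membrane proteins in cilia, was at 4.09 ± 0.856 FPKM in wild type and 7.20 ± 1.37 in the mutant (SD, n = 3; log2 difference 0.69, adjusted p = 0.442, limma). invs, which encodes inversin, had a log2 difference of 0.48 and tmem17 of -0.25, neither past the threshold. The intraflagellar transport genes, which carry cargo along cilia, had a mean log2 difference of 0.15, with 23 of 24 members positive (adjusted p = 0.0453, camera of limma; adjusted p = 0.848 with an estimated correlation). Their mean was -0.00905 without wild type 3 and 0.0422 without mutant 3 (adjusted p = 0.497), and without mutant 2 it stayed at 0.157 with the call lost (adjusted p = 0.129, camera of limma). Among them kif3a, a motor subunit, differed by 0.35, dync2li1 by 0.22, wdr35 by 0.29 and ift88 by 0.30 on the log2 scale, and none passed the threshold. Over the 16 alternatives these 4 genes kept their direction, with lowest values of 0.18, 0.078, 0.10 and 0.12 in the same order. Having been chosen by smallest p in the same libraries, they give no independent support by this.

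The meiotic prophase genes had a mean log2 difference of 0.12, with 24 of 32 positive (adjusted p = 0.0453, camera of limma; adjusted p = 0.848 with an estimated correlation). Without wild type 3 their mean was -0.0283, and the call was also lost without mutant 2 (mean 0.104, adjusted p = 0.138) and without mutant 3 (mean 0.103, adjusted p = 0.173, camera of limma). dmc1, the meiotic recombinase, was at 167 ± 10.4 FPKM in wild type and 230 ± 32.6 in the mutant (SD, n = 3; log2 difference 0.46, adjusted p = 0.464, limma). Its cofactor gene mnd1 differed by 0.51 and the helicase gene hfm1 by 0.44, whereas terb2, which ties telomeres to the nuclear envelope, differed by -0.69. The cell cycle list had a mean of 0.15, with 42 of 50 positive (adjusted p = 0.00363, camera of limma), and the DNA repair list a mean of 0.14, with 47 of 56 positive (adjusted p = 0.00312, camera of limma). For both lists the adjusted p was 0.848 with an estimated correlation, and without wild type 3 their means were 0.00889 and 0.0288. The log2 differences of their leading members were 0.43 for ncapg (condensin), 0.31 for nuf2 (kinetochore), 0.59 for rrm1 (ribonucleotide reductase), 0.48 for top2a (topoisomerase), 0.45 for pms1, 0.31 for XPA, 0.35 for rad50 and 0.33 for fancc. None of these passed the threshold over all genes. Over the 16 alternatives they kept their direction, with lowest values of 0.28, 0.23, 0.24, 0.21, 0.24, 0.26, 0.19 and 0.15 in the same order. They were chosen by smallest p in the same libraries, so a kept direction is no independent support.

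The interferon and complement list was lower by a mean log2 difference of -0.39, with 23 of 28 members negative (adjusted p = 0.000726, camera of limma; adjusted p = 0.848 with an estimated correlation). MX1, an antiviral GTPase, was at 8.81 ± 6.26 FPKM in wild type and 1.91 ± 1.17 in the mutant (SD, n = 3; log2 difference -1.64, adjusted p = 0.490, limma). psmb8, a subunit of the immunoproteasome whose span overlaps genes of the MHC on the other strand, differed by -0.95. It was at 42.7 FPKM in wild type 3 against 19.0 and 20.8 in wild type 1 and 2. Over the 16 alternatives its difference shrank to as little as -0.59. Adjusted over the list alone, 2 members passed. They were c7b, a complement component, at 4.84 ± 0.947 and 1.17 ± 0.690 FPKM (adjusted p = 0.0156 over the list, limma), and masp2, a protease that starts the lectin pathway, at 0.969 ± 0.240 and 4.02 ± 0.793 FPKM (adjusted p = 0.00671 over the list, limma). masp2 was higher in the mutant, against the direction of its list. The ribosomal protein list had a mean of -0.11, with 59 of 65 negative (adjusted p = 0.000726, camera of limma; adjusted p = 0.848 with an estimated correlation). Its mean was 0.0186 without wild type 3 and -0.0661 without mutant 2 (adjusted p = 0.0913, camera of limma). The genes rpl10, rps3a, rpl17 and rplp2 differed by -0.34, -0.25, -0.24 and -0.26. Over the 16 alternatives these values shrank to as little as -0.15, -0.14, -0.088 and -0.071. In the other 6 called lists, 0 members passed when adjusted over the list alone.

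Without wild type 3, interferon and complement alone of the 7 was called (mean -0.27, adjusted p = 0.0339, camera of limma). In the same fit, the extracellular matrix list (mean 0.32) and the endothelium and smooth muscle list (mean 0.59) were called higher, both at an adjusted p of 9.03e-06 in camera of limma. None of these 3 calls held with an estimated correlation (adjusted p = 0.997 for each, camera of limma) or with fry (adjusted p = 0.983 for each). Without wild type 1, 11 lists were called. Without mutant 3, the mean of interferon and complement was -0.25 (adjusted p = 0.0248, camera of limma).

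The other 19 lists were not called with all libraries. Their adjusted p in camera of limma was 0.0770 for extracellular matrix, for endothelium and smooth muscle and for Hippo, 0.0852 for the motile axoneme (44 of 56 members positive), 0.103 for other organs, 0.140 for blood, 0.170 for spermiogenesis, 0.230 for macrophages and lymphocytes and for stress genes, 0.287 for apoptosis, 0.360 for glycolysis, 0.442 for oxidative phosphorylation, and 0.848 for cell junctions. It was 0.994 for spermatogonia, Sertoli cells, Leydig cells, ovary, hedgehog and Wnt. Adjusted over the list alone, 5 of their members passed: tfr1b of blood (higher), rgs5b of endothelium and smooth muscle (lower), btg4 (higher) and lhx8 (lower) of the ovary list, and junba of the stress list (lower). The mean, the median and the test differed in sign for spermatogonia (mean -0.04, median 0.01, test up), Leydig cells (mean 0.02, test down), ovary (mean 0.03, median -0.04), hedgehog (mean -0.01, median 0.04) and glycolysis (mean -0.00, median 0.12).

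**Figure D2:**
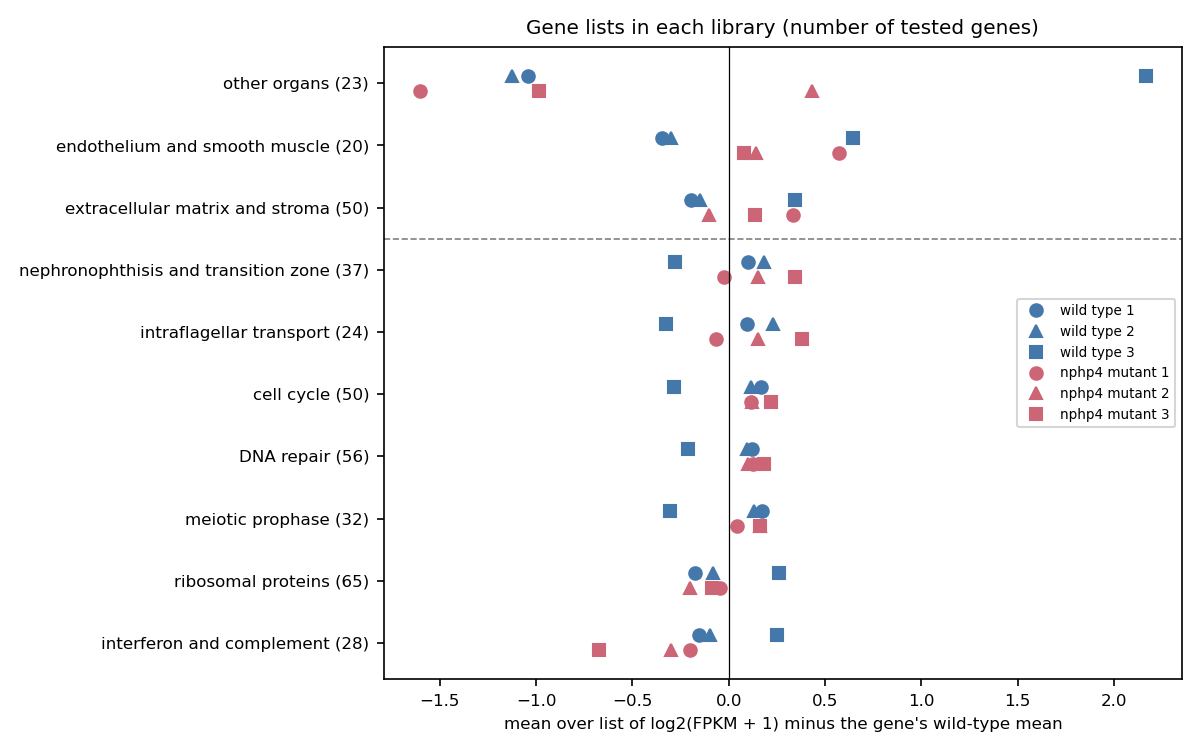
Mean over each list of log2(FPKM + 1) minus the gene's wild-type mean, in each library (6 points per list; number of tested genes in brackets), for the 7 called lists and, above the dashed line, 3 lists not called. Wild type 3 lies at 2.17 in the list of other organs, where wild type 1 and 2 lie at -1.04 and -1.12.

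No chromosome held more called genes than the others after adjustment. Chromosome 13 carried 3 of the 9 (Fisher's exact test, p = 0.00457, adjusted p = 0.114), and chromosome 11 carried 2 (adjusted p = 0.662). Within 5 Mb of nphp4, 0 of 112 tested genes were called by limma, and 6 (5.36%) had an unadjusted p below 0.05 against 7.14% elsewhere (Fisher's exact test, p = 0.582).

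Genes with an unadjusted p below 0.05, a threshold chosen after the data were seen, were concentrated on chromosome 1, the chromosome that carries the sex-determining region of medaka. It held 115 such genes among 803 tested (14.3%), against 6.73% elsewhere (Fisher's exact test, adjusted p = 6.51e-12). Chromosome 9 (4.11%, adjusted p = 0.00543) and chromosome 22 (4.33%, adjusted p = 0.0281) held fewer than the rest by the same test, and the mitochondrial genome held 5 of 23 (21.7%, adjusted p = 0.0734). A search along chromosome 1 for the point of largest contrast in this share placed it near 8.52 Mb, at commd1. The share was 7 of 222 genes (3.15%) before that point and 108 of 581 (18.6%) after it, 72 higher and 36 lower. Since the point was chosen for its contrast, these shares may overstate the step. The genes past it varied in size of change. The 108 genes included tyrp1b, a pigment enzyme, at 4.72 ± 0.662 FPKM in wild type and 22.2 ± 10.1 in the mutant (SD, n = 3, adjusted p = 0.139, limma). They also included junba, a transcription factor, at 7.31 ± 0.497 and 1.79 ± 0.828 FPKM (adjusted p = 0.139, limma). 0 genes of chromosome 1 were called by limma.

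**Figure D3:**
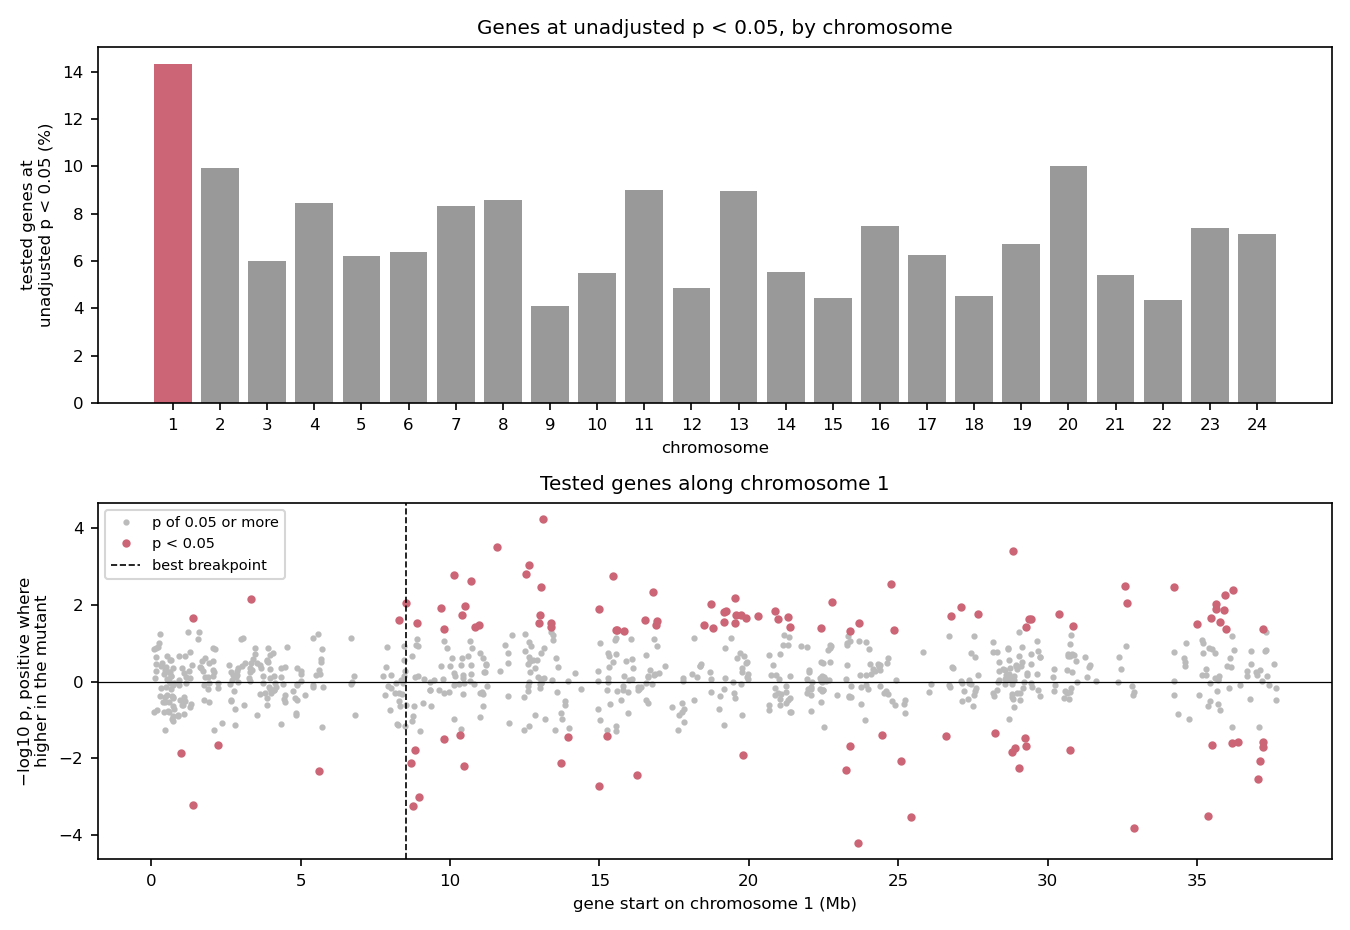
Upper panel: share of tested genes at an unadjusted p below 0.05 on each nuclear chromosome (bars, percent), highest on chromosome 1 at 14.3%; the mitochondrial genome is not drawn. Lower panel: each tested gene of chromosome 1 by start (Mb) and by -log10 p, plotted upward where higher in the mutant, with the best breakpoint near 8.52 Mb dashed.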

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

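The alternatives with TMM scaling, quality weights, the intestinal covariate, both libraries left out and matching of lists also by Swiss-Prot name were chosen only after the results were seen, and the others before. The level of nphp4 kept its direction in all 16 alternatives (log2 difference -1.22 to -0.77, adjusted p in limma 0.0844 to 0.966) and was called in none. The excess on chromosome 1 also stayed in all 16 (9.89% to 19.7% of its tested genes). With 9 genes called in limma, 5 higher and 4 lower, TMM scaling and a fold minimum called the same 9, and scaling by median-ratio factors moves nothing. Library totals called 14 (7 lower) and the filter of 1 CPM 16 (9 lower and 11 lists), each with all 9 among them. Testing without a filter called 3 higher genes and 12 lists, and a pseudocount of 0.1 called 3 higher genes. limma-voom called 0 genes, 0 higher and 0 lower, with 1042 at an unadjusted p below 0.05. At an FDR of 0.01, 5 genes remained (2 higher). The cause of these differences was not tested, except that a stricter FDR keeps fewer genes. Of 16 alternatives, RF00001 and ENSORLG00000023131 kept their direction and call in 15, ENSORLG00000012644 in 12, ENSORLG00000026380 in 11, ENSORLG00000022373 in 10, si:ch211-132b12.2 in 9, LSAMP and ENSORLG00000029944 in 8 and ENSORLG00000029947 in 7, and in the rest they lost the call and kept their direction, at 0.892 to 2.17 of the log2 difference with all libraries in limma-trend.

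Leaving out 1 library at a time gave 2 to 18 called genes, 0 to 7 higher and 2 to 11 lower, and 3 to 11 called lists. Without wild type 3, 18 genes with all 9 among them and 3 lists were called. Without wild type 1, 4 genes and 11 lists were called, and without mutant 1, 2 and 3, 3, 2 and 2 genes. Fewer samples enter these fits. Quality weights, which gave wild type 3 a weight of 0.283, called 41 genes (14 higher, 27 lower, all 9 among them) and 2 lists. The intestinal covariate called 20 genes (13 lower, all 9 among them) and 3 lists. Without both libraries that held intestinal transcripts, 3 genes were higher and 7 lower, 3 lists were called, and 1 chromosome, number 11, was enriched in called genes (adjusted p = 0.0145, Fisher's exact test). An estimated correlation called 0 lists, and fry called 0. Matching also by Swiss-Prot name called 9.

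Of the 7 called lists, 4 changed direction in the test, each where wild type 3 was left out or given less weight. Lists that were not called changed direction in other fits too, such as the motile axoneme (list motile axoneme and dynein assembly) with a mean of -0.0221 without mutant 3. Intraflagellar transport had mean log2 differences of -0.00905, -0.0122 and -0.00648 without wild type 3, with quality weights and without both libraries, the list meiotic prophase had -0.0283, -0.0215 and -0.0477, and ribosomal proteins 0.0186, 0.0204 and 0.0635. With 1 library left out at a time, these 3 means ranged from -0.00905 to 0.271, from -0.0283 to 0.209 and from -0.199 to 0.0186. The nephronophthisis list was tested as lower at means of 0.0104 with weights and 0.0192 without both libraries. The cause was not tested. Of 19 alternatives, the 7 called lists kept their direction and call in 10 to 16, and extracellular matrix was called in 11 and endothelium and smooth muscle in 9. The interferon and complement list kept its direction throughout (adjusted p 2.75e-06 to 0.875).

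Pairing is not stated. Same-numbered libraries' deviations correlated at 0.31, -0.56 and -0.42. This cannot decide: wild type 3 and mutant 2, both with intestinal transcripts, reached 0.61. With the replicate block, 6 genes were called, 1 of them higher, 4 of them shared with the 9, and 11 lists. The count-based fits planned for raw counts were not run, since the values were FPKM. At 13438879 to 16054354 reads per library a gene with no read in 1 group has only a lower bound to its fold.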

Other observations

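The limma comparison and the fits without wild type 3 were planned before the data were examined. The tests of library splits, breakpoints, copy number, neighbours, depth, the ice-structuring family and other tissue lists, and the reading of the fits without wild type 3 as tests of an explanation, were chosen after the results were seen.

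Some abundant or well-known genes separated the groups without passing the threshold over all genes. The MHC class I gene orla-uaa was at 556 ± 285 FPKM in wild type and 64.0 ± 37.6 in the mutant (SD, n = 3; adjusted p = 0.195, limma). cck, a peptide hormone gene, was at 27.4 ± 6.70 and 7.44 ± 1.61 FPKM (adjusted p = 0.0889, limma). mos, a kinase of meiosis, was at 10.2 ± 2.98 and 3.55 ± 0.444 FPKM (adjusted p = 0.195, limma). 3 melanin genes were higher in the mutant: pmela at 4.63 ± 1.11 and 14.7 ± 3.01 FPKM (adjusted p = 0.126, limma), TYRP1 at 3.39 ± 0.208 and 10.4 ± 2.76 (adjusted p = 0.126, limma), and tyrp1b at 4.72 ± 0.662 and 22.2 ± 10.1 (adjusted p = 0.139, limma). A separate list of 15 pigment cell genes was not called (mean log2 difference 0.036, adjusted p = 0.267, camera of limma). Of its members, 3 were higher and 0 lower in the mutant at an unadjusted p below 0.05 in limma.

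There were 10 ways to split the 6 libraries 3 against 3, too few for a share below 0.05. The real split called 9 genes, 5 higher and 4 lower, and each of the other 9 called 0 in limma, with 166 to 1362 genes at an unadjusted p below 0.05 against 1084 in the real split. So 1 split reached each of these 3 counts. For gene lists the real split called 7 and the highest other 15, and 8 of the 10 splits called at least as many. The share of chromosome 1 genes at an unadjusted p below 0.05 was 14.3% in the real split and 8.35% in the highest other, so 1 split reached it.

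The first pattern is the excess of small p-values on chromosome 1. Intestinal transcripts in wild type 3 are argued against, since the share was 16.1% without that library. Another copy number of the region in the mutant is argued against by the median log2 difference of its 581 tested genes, 0.0673 (95% bootstrap interval 0.0409 to 0.0988), far below that of an added copy. A chromosome segment that differed in sequence between the fish of the groups stays open: the best breakpoint had a permutation p of 1e-04, the smallest that 10000 permutations give (adjusted p = 0.0024, beside 0.0036 on chromosome 20 and 0.0096 on chromosome 2). Splits of the libraries that mix the genotypes also gave a breakpoint on chromosome 1, with a smallest permutation p of 4e-04, so that p alone does not decide. That split had 8 genes at an unadjusted p below 0.05 on the chromosome, with the breakpoint at 0.638 Mb. The real split had 115, with the breakpoint at 8.52 Mb. Wild type 1 and 2 with mutant 3 against the rest gave 66, and the share fell from 12.4% to 5.17% at 13.2 Mb (permutation p = 0.015). An effect of nphp4 itself stays open and untested.

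The second pattern is that 6 of the 7 called lists lost their call without wild type 3, where their means shrank to between -0.0283 and 0.0288, whereas 4 lost it without mutant 2 (2 of them with no smaller mean) and 3 without mutant 3. Library depth is argued against for wild type 3, since its 15516979 reads lie within the range of the other 5, and stays open for mutant 2 with the fewest reads (13438879) and mutant 3 with the most (16054354). Intestine and exocrine pancreas in the sample may account for the part of wild type 3: 18 of 19 intestine genes and 12 of 12 pancreas genes were highest in wild type 3, with median levels of 14.0 FPKM against 0.270 to 2.44, and 1279 FPKM against 14.1 to 206, in the other libraries. Of these genes, 3 and 5 also stand in the earlier lists, and 3 and 10 reached 1 FPKM in all other 5 libraries. Of the 7 called lists, 1 (interferon and complement) was called in the same direction without wild type 3. With an estimated correlation it was not called in that fit (adjusted p = 0.997, camera of limma). Whether genotype moves any of the 7 stays open.

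Among the other tissue lists, wild type 3 was highest in 3 of 5 liver genes, 6 of 9 kidney tubule genes, 1 of 8 skeletal muscle genes and 5 of 15 pigment cell genes. In camera of limma the intestine (adjusted p = 0.00470), pancreas (adjusted p = 0.0126) and liver lists (adjusted p = 0.0126) were lower in the mutant, and the kidney (adjusted p = 0.429) and muscle lists (adjusted p = 0.926) were not called. With an estimated correlation the unadjusted p of the first 3 was 0.395, 0.424 and 0.153. Without wild type 3 the unadjusted p in camera of limma was 0.773, 0.593 and 0.0538. Mutant 2 had the next highest level of the intestine genes after wild type 3, with a median of 2.44 FPKM. For the pancreas genes mutant 3 came next after wild type 3, with a median of 206 FPKM. Mutant 2 followed at 152 FPKM, and mutant 1 was lowest at 14.1 FPKM.

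The third pattern is that genes with small p-values were neighbours, most of which did not pass the threshold over all genes. Of the 72 genes with an unadjusted p below 0.001 in limma, 15 had such a neighbour of another protein within 200 kb, against a mean of 3.72 for permuted positions (permutation p = 8e-04), and the highest other split of the libraries had 12; with overlapping genes not counted as neighbours these values were 13, 3.65, 0.0021 and 11. The 15, of which 4 were called, included CDCA7L (41.1 ± 15.8 and 11.7 ± 1.30 FPKM, wild type and mutant), whose span holds both called ice-structuring genes on chromosome 11 and which may share reads with them, vwa7 beside si:ch211-132b12.2 on chromosome 13, and exosc10 beside masp2 on chromosome 7 (14.5 ± 1.97 and 40.8 ± 10.8 FPKM). Without wild type 3, 15 of the 15 genes with a neighbour had an unadjusted p below 0.05 in limma in the same direction. They had been chosen at a p below 0.001 with that library included, so this does not decide on its intestinal transcripts. Neighbours were not counted anew without wild type 3. Reads moved between the 4 ice-structuring copies are argued against, since their summed FPKM in the highest mutant library was 0.136 of the lowest wild-type library. Sequence differences between the fish of the groups near these genes stay open: splits that mix the genotypes also gave up to 12 such genes, so the permutation p does not decide, and the sequences of the reads were not analysed here.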
